A study of Mus musculus with 18 samples.

How the data were processed

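Gene expression was measured by RNA sequencing in 18 libraries of primary alveolar macrophages from male C57BL/6JRj mice. Per the labels, the cells spent 5 days in culture, in DMEM with 10% fetal bovine serum and an antibiotic-antimycotic mix, at 37 °C and 5% CO2. They met particles for 4 of these days. The particles were G1-1, a titanium dioxide, and Printex90, a carbon black. Each particle had a control, a non-overload and an overload condition, which gave 6 groups of 3 biological replicates, and each particle had its own 3 control libraries. The labels state no dose for either condition. The authors extracted total RNA with DNase digestion and prepared libraries from 150 ng of it after depletion of ribosomal RNA.

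The deposited table holds expected counts, the read counts that Salmon estimates per gene, with 1 column per library and no scaling between libraries. The authors list FastQC, MultiQC and Salmon without versions, and the genome build GRCm39. The annotation and the step from transcripts to genes are not stated. The table identifies genes by symbol alone. The reference annotation at hand was of another build, so no coordinates are given. Of 35682 entries, 94 had no gene name and were left out of the tests. Values were rounded to whole numbers.

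The libraries were compared with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 14728. Scaling was by TMM, and 1 quasi-likelihood model (glmQLFit, glmQLFTest) with a mean per group was fitted to all 18 libraries, with 12 residual degrees of freedom. P values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are fitted log2 values. Their standard error (SE) is approximate: the size of the log2 change divided by the square root of the F statistic of its test. At counts near 0 it has little meaning. Levels are normalised CPM, counts scaled to 1 M per library, as mean ± SD of 3 libraries. Gene lists were fixed before the data were examined, 40 in number, for pathways, cell types and signs of RNA quality. The 36 with at least 5 tested members were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 36 lists, and again with the correlation estimated per list. The lists of nuclear-retained noncoding RNAs, B cell markers, erythroid markers and mast cell, basophil and eosinophil markers had too few tested members (2, 4, 0 and 2) and have no test. For each list, the members called over all genes and those called when adjusted over the list alone were counted. The procedure fry was run as a description of whether the members of a list moved one way.

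The text names genes by a rule that was also fixed before the data were examined. In each comparison of overload with control, these are the 8 genes with the largest rise and the 8 with the largest fall, and in each other comparison the 5 and 5. They had an adjusted p under 0.05, a mean of at least 2 CPM, a symbol that is not a predicted model, and all 3 libraries of one group beyond all 3 of the other. Chance gives such a separation for 10% of genes. In interactions, separation was not required. The rule adds up to 4 members of each list with the lowest p, called or not, and 30 genes that are reported in any case. Any other gene is said to be chosen after its values were seen.

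Of the libraries, 17 held 35.2 to 70.7 M estimated counts, and Printex90 overload replicate 1 held 0.475 M (M, 10 to the power of 6). A total of 3 counts, used as the detection floor, was 0.0422 to 0.0849 CPM in the 17 and 6.22 CPM in the shallow library. Intervals given for ratios of pooled counts are exact at 95% and, like the floors, cover counting error only. The pipeline was tested on simulated data with 3 libraries per group. In a simulated G1-1 overload comparison, 68.7% of genes set to change 1.5-fold, 77.6% of those at 2-fold and 97.0% of those at 4-fold were called, with 5 false calls among 200. In a simulated Printex90 overload comparison the shares were 61.2%, 83.6% and 98.5%, with 10 false calls among 207. The genes set to change were not drawn from those with the lowest levels. Counts were simulated as independent between genes, with no structure among the libraries of a group. These shares may therefore overstate what is recovered in the real libraries.

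The alternatives were RLE size factors, DESeq2 1.42.0, no filter and a stricter filter on low counts (1 CPM in 3 libraries), the 9 libraries of a particle alone, the replicate number as a block, a test against a fold of 1.5 (glmTreat), the estimated correlation for lists, and each library left out in turn. After the data were seen, 2 more were added: leaving out Printex90 overload replicate 1 everywhere, and leaving it out with a score of fibroblast and smooth muscle markers (mean of log2(CPM + 1) over the list) as a covariate. Correlations between effects were computed across genes, which are not independent replicates, and those that share control libraries were set beside 40 simulations of unchanged groups.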

Results

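The study asks how alveolar macrophages, the phagocytes of the airspaces, respond to particle overload, and these libraries are its mouse part. Cultured mouse cells were exposed to G1-1 titanium dioxide or Printex90 carbon black at a non-overload or an overload condition, each with 3 control libraries of its own. The G1-1 libraries held 43.6 to 70.7 M estimated counts (M, 10 to the power of 6). The Printex90 libraries held 35.2 to 63.8 M, apart from Printex90 overload replicate 1 at 0.475 M, which the median of the other 17 libraries exceeded 108-fold. In that library 9112 genes were detected, against 14999 to 17006 in the others. Markers of fibroblasts and smooth muscle varied between libraries within groups. Their score was above 1.8 in G1-1 control 1, G1-1 non-overload 2, Printex90 control 2 and Printex90 overload 2 and 3. In G1-1 control 1, Col1a1 stood at 47.9 CPM and Acta2 at 61.5 CPM, against 2.08 and 4.98 CPM in G1-1 control 3.

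**Figure D1:**
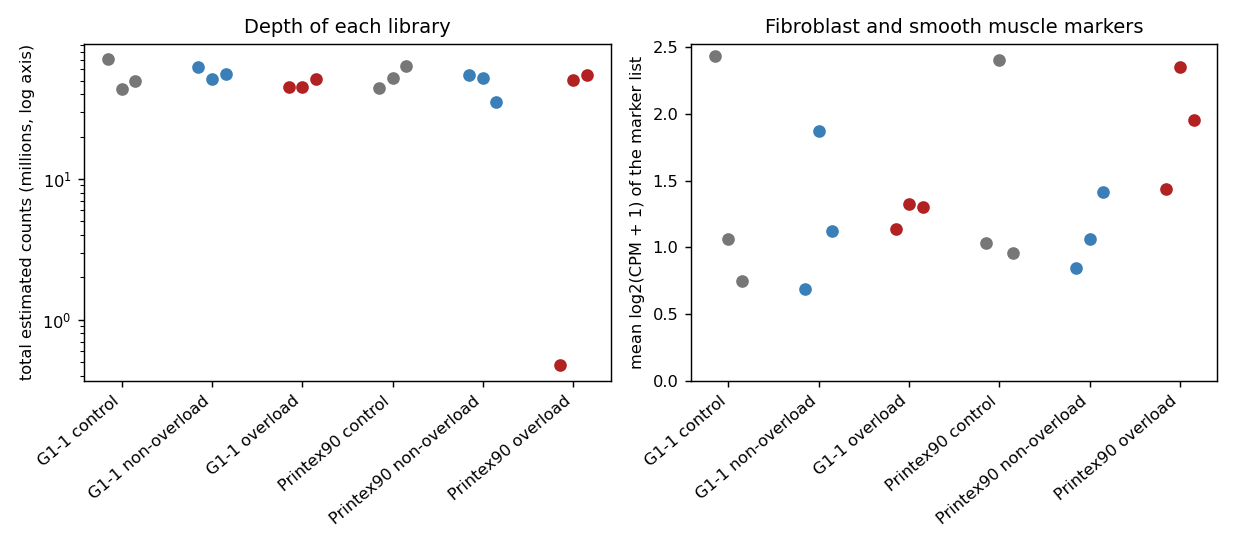
Depth and marker score of each of the 18 libraries, 3 points per group. The left axis is the total of estimated counts (M, log scale), with Printex90 overload replicate 1 at 0.475 M, and the right axis is the mean of log2(CPM + 1) over the fibroblast and smooth muscle list, from 0.689 in G1-1 non-overload 1 to 2.44 in G1-1 control 1.

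Genes of cholesterol synthesis fell in macrophages under G1-1 overload against their controls. Cyp51, the lanosterol demethylase, fell from 117.6 ± 3.97 to 82.95 ± 5.02 CPM (SD, n = 3 each; log2 change -0.50, SE 0.0638, edgeR adjusted p = 0.00268). Insig1, which retains the sterol-responsive transcription factors in the endoplasmic reticulum, fell from 211 ± 4.63 to 156.2 ± 4.72 CPM (-0.43, SE 0.0556, edgeR adjusted p = 0.00268). Idi1 and Fdps, an isomerase and a synthase of the same pathway, fell by 0.55 and 0.36 on the log2 scale. Of 24 tested members of the list, 9 fell over all genes and 15 when adjusted over the list alone. The 9 were 2 without G1-1 control 1, control 2, overload 1 or overload 3 and with the replicate block, 4 without control 3, 3 without overload 2 and 12 without Printex90 overload 1, while the 15 stayed at 13 to 18. The median change was -0.32, camera gave an adjusted p = 2.57e-42, and it was 0.00035 with an estimated correlation. The list also fell in all 11 alternatives in which it was tested with the preset correlation.

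The other genes that changed under G1-1 overload were of several kinds. Msr1, a macrophage scavenger receptor, rose from 28.02 ± 2.18 to 43.76 ± 5.93 CPM (1.56-fold, log2 change 0.65, SE 0.122, edgeR adjusted p = 0.0437). Pla2g7, a phospholipase that degrades platelet-activating factor, rose 1.62-fold, and Rapgef5, an exchange factor for Rap proteins, 1.48-fold. Cyfip2, a part of the WAVE complex that drives actin branching, rose 1.31-fold (edgeR adjusted p = 0.0088), and the cytoplasmic actin Actg1 rose 1.15-fold. Clmn rose 1.28-fold and Septin8, a septin, 1.19-fold. The largest fall was that of Rpl22l1, a ribosomal protein paralog (-0.80, SE 0.147), followed among the genes outside cholesterol synthesis by the chitinase-like protein Chil3 (-0.59), Pald1 (-0.54) and the cytokine Il18 (-0.47). Among the genes reported in any case, the cell cycle inhibitor Cdkn1a (0.63, SE 0.128) and the metallothionein Mt2 (0.67, SE 0.135) did not pass (edgeR adjusted p = 0.062 each). The changes of Tnf, Il1a, Hmox1, Spp1 and Gpnmb, between -0.01 and 0.19, did not pass either.

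In all, 22 of 14728 genes changed with G1-1 overload, 7 up and 15 down, and 1110 genes had an unadjusted p under 0.05 against 736 that chance gives. The changes called were 0.20 to 0.80 on the log2 scale in size, and none passed a test against a fold of 1.5. The count depended on single libraries. It was 3 without G1-1 control 1, 8 without control 2, 3 without overload 1, 4 without overload 2 and 2 without overload 3. It was 81 (38 up, 43 down) without Printex90 overload replicate 1, which is not in this comparison but shares its estimate of the spread. DESeq2 called 111. Apart from the test against a fold of 1.5, Cyp51 and Insig1 were called in all 14 alternatives (highest adjusted p 0.0364 and 0.0374). Each of the other 20 genes was lost in at least 5 of the 14.

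Beyond cholesterol synthesis, 10 lists passed camera's preset test in G1-1 overload, and none held with an estimated correlation. Glycolysis and hypoxia genes rose, with 0 of 27 members called over all genes and 17 higher when adjusted over the list alone (median 0.29, camera adjusted p = 9.44e-19, adjusted p = 0.106 with an estimated correlation). Examples are the glucose transporter Slc2a1 (0.44, SE 0.112) and the enolase Eno1 (0.38, SE 0.0957), neither of which passed over all genes. Metal and iron handling genes rose with 3 of 19 higher over the list alone (camera adjusted p = 0.00341, 0.106 with an estimated correlation as adjusted p). NF-kB feedback and target genes rose with 2 of 27 higher over the list alone and 0 over all genes, and matrix remodelling genes with 3 of 31 and 0 (camera adjusted p = 0.0394 each, adjusted p = 0.705 each with an estimated correlation). Lists that fell were proliferation (median -0.22, 0 of 40 called), cytosolic ribosomal proteins (-0.12, 3 of 48 lower over the list alone), mitochondrially encoded transcripts (-0.22, 0 of 13 called) and nuclear-encoded oxidative phosphorylation (-0.05, 0 of 43 called), with adjusted p = 0.705 to 0.731 with an estimated correlation. The alveolar macrophage identity list fell with 2 of 32 members called over all genes, Chil3 and Il18, and 4 lower over the list alone (camera adjusted p = 0.0247, adjusted p = 0.705 with an estimated correlation). Markers of monocytes and interstitial macrophages fell with 1 of 12, again Chil3, called over all genes, and 2 lower and 1 higher over the list alone (camera adjusted p = 0.0174, adjusted p = 0.268 with an estimated correlation). Fibroblast and smooth muscle markers had a median of -0.70 and did not pass (camera adjusted p = 0.501). The count of 11 lists was 6 without G1-1 control 3 and 7 without overload 3.

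Of these lists, cholesterol synthesis and glycolysis and hypoxia kept the preset call without any single library, and the other 9 did not. Proliferation had a median of -0.06 without G1-1 control 1 (camera adjusted p = 0.543) and -0.17 without overload 1 (0.247). Ribosomal proteins had one of -0.04 without control 2 (camera adjusted p = 0.178) and -0.22 without control 3 (2.6e-26), and their 3 members lower over the list alone were 22 without control 3 and 1 without control 1, control 2 or overload 1. The median of oxidative phosphorylation was -0.01 without control 2 (camera adjusted p = 0.497), with calls also lost without control 1 (0.0595) and overload 1 (0.0852). The median of the alveolar macrophage identity list turned to 0.00643 without overload 2 (camera adjusted p = 0.252), and the call was lost without control 2 (0.246) and control 3 (0.205). Mitochondrially encoded transcripts lost it without control 3 (camera adjusted p = 0.0819) and overload 2 (0.389) and had a median of -0.41 without overload 1, with 2 lower over the list alone. The call was lost for monocyte markers without control 1 (camera adjusted p = 0.0618) and overload 3 (0.082), and for metal and iron genes without control 3 (0.062) and overload 3 (0.0542). NF-kB genes lost it without control 1, 2 or 3 or overload 2 or 3 (camera adjusted p = 0.0588 to 0.252), and matrix genes without control 3 or overload 1 or 3 (0.0852 to 0.436).

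G1-1 at the non-overload condition changed no gene past the threshold. The cholesterol list was lower here too, with 23 of 24 members below their controls, a median of -0.13 and 1 member lower when adjusted over the list alone (camera adjusted p = 1.53e-12, adjusted p = 0.0566 with an estimated correlation). That count was 7 without non-overload 3, 2 without Printex90 overload 1 and 0 without non-overload 1. The list of liver X receptor targets and cholesterol efflux also holds genes of fatty acid synthesis, such as Scd1 and Fasn. It fell with a median of -0.10, with 2 of 17 members lower over the list alone and 0 over all genes (camera adjusted p = 5.35e-05, adjusted p = 0.0566 with an estimated correlation). The 2 were 0 without control 1, control 2 or non-overload 1 and 1 without non-overload 2 or 3. Among list members, the metalloprotease Adam8 stood at 27.7 ± 4.62 CPM against 10.0 ± 0.908 (SD, n = 3 each; log2 change 1.47, SE 0.271, edgeR adjusted p = 0.24), the integrin chain Itgam at 142 ± 21.1 against 85.0 ± 9.82 CPM (0.74, edgeR adjusted p = 0.24) and the interleukin antagonist Il1rn at 108 ± 15.2 against 64.3 ± 6.45 CPM (0.75, edgeR adjusted p = 0.24). Of the 31 matrix remodelling genes, 4 were higher when adjusted over the list alone and 0 over all genes. EdgeR called 0 of 14728 genes, with 481 at an unadjusted p under 0.05, and DESeq2 called 12. Without Printex90 overload replicate 1 edgeR called 1. Of the lists, 9 passed the preset test, and 3 passed without G1-1 control 2. Among the 9 were glycolysis and hypoxia (up, median 0.14, 0.25 without control 2 and 0.09 without non-overload 1), monocyte and interstitial macrophage markers (down, -0.19, camera adjusted p = 0.0449) and mitochondrially encoded transcripts (up, 0.14, camera adjusted p = 0.0374), with adjusted p = 0.581, 0.581 and 0.751 with an estimated correlation. The monocyte call was lost without any single G1-1 library but non-overload 2 (camera adjusted p = 0.0719 to 0.143), and the mitochondrial one without control 1 or 2 or non-overload 1 or 2 (0.09 to 0.525). The monocyte median ran from -0.16 without control 1 to -0.35 without control 2. The mitochondrial median ran from 0.05 without control 1 to 0.24 without control 3. None of the 9 lists passed with an estimated correlation. The fall of cytosolic ribosomal proteins (median -0.08, camera adjusted p = 9.62e-05, adjusted p = 0.751 with an estimated correlation) was lost without G1-1 control 2 or without non-overload 3 (camera adjusted p = 0.977 and 0.155), while without control 3 the median was -0.18 with 10 of 48 lower over the list alone against 0 (camera adjusted p = 1.11e-19).

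Between the exposure conditions of G1-1, Insig1 was lower in overload than in non-overload (156.2 ± 4.72 against 200.9 ± 5.37 CPM, SD, n = 3 each; log2 change -0.36, SE 0.0556, edgeR adjusted p = 0.048) and Cyfip2 was higher (295 ± 1.54 against 231.3 ± 7.9 CPM; 0.35, SE 0.0557, edgeR adjusted p = 0.048). The cholesterol list was lower in overload, with 1 of 24 members called over all genes and 10 when adjusted over the list alone (median -0.18, camera adjusted p = 2.38e-14, adjusted p = 0.0434 with an estimated correlation). The 1 was 0 without any single library of the 6, and the 10 were 2 without non-overload 2 and 6 without non-overload 3. Mitochondrially encoded transcripts fell with 5 of 13 lower over the list alone and 0 over all genes (median -0.38, camera adjusted p = 1.86e-09, adjusted p = 0.272 with an estimated correlation). Their median was -0.19 without overload 2, and the 5 were 2 without overload 2 or non-overload 1, 3 without non-overload 2 and 9 without overload 1 (median -0.53). Lysosome genes were higher in overload with 3 of 51 over the list alone and 0 over all genes, and the liver X receptor targets with 3 of 17 higher and 1 lower over the list alone and 0 over all genes (camera adjusted p = 0.000221 and 0.00179, adjusted p = 0.658 and 0.178 with an estimated correlation). Neither list passed in overload against controls (medians 0.0107 and 0.00547, camera adjusted p = 0.289 and 0.82). Both were lower in non-overload against controls. There the lysosome list had a median of -0.04 (camera adjusted p = 0.0179, 0.751 with an estimated correlation). Its call was lost without control 2 or non-overload 3 (camera adjusted p = 0.969 and 0.112), and its median was -0.08 without control 3. The acid hydrolases Gaa (0.26) and Ctsd (0.13) and the inhibitor Cdkn1a (0.68) did not pass over all genes. Insig1 and Cyfip2 were the only calls among 923 genes with an unadjusted p under 0.05. DESeq2 called 38, edgeR 19 without Printex90 overload replicate 1, and edgeR called 0 without any single library of G1-1 non-overload (1, 2 or 3) or overload (1, 2 or 3). Of the lists 10 passed the preset test, 7 up and 3 down. They include immediate early genes, a sign of handling, which were higher with 1 of 20 over the list alone and 0 over all genes (median 0.12, 0.07 without overload 2 or 3, camera adjusted p = 0.00767), and proliferation, which was lower with 0 of 40 called (median -0.33, -0.22 without non-overload 2, camera adjusted p = 1.11e-05), with adjusted p = 0.262 and 0.609 with an estimated correlation. The cholesterol list was the only one to pass with an estimated correlation.

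Cyp1b1, a cytochrome P450 that oxidises aromatic hydrocarbons and steroids, almost vanished from the macrophage cultures under Printex90 overload. It stood at 7.49, 18 and 5.21 CPM in the 3 controls and at 0, 0.0200 and 0.0187 CPM in the 3 overload libraries, from 0, 1 and 1 counts. The 0 is that of the shallow library, whose floor of 6.22 CPM lies above 1 of the controls, so overload 2 and 3 carry the result. Pooled over the libraries, its level was 0.191% of that in the controls (2 against 1613 counts). The 95% exact interval, of counting error only, was 0.0232% to 0.693%. The edgeR test gave an adjusted p = 0.000663, and the fitted log2 change of -8.88 (SE 0.983) is no bound at such counts. Ftl1, the ferritin light chain, rose from 14100 ± 74.2 to 17450 ± 466 CPM (SD, n = 3 each; 1.24-fold, log2 change 0.31, SE 0.0455, edgeR adjusted p = 0.0192). Pld4, a lysosomal nuclease, fell from 23.57 ± 1.05 to 15.24 ± 0.625 CPM (-0.60, SE 0.0984, edgeR adjusted p = 0.0477). At this level the shallow library holds few counts, so the small SD in overload does not measure how well the replicates agree. Reads of Ftl1 can be shared with its pseudogenes, which leaves its level uncertain.

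These 3 genes, 1 up and 2 down, were all that edgeR called in Printex90 overload, with 658 genes at an unadjusted p under 0.05 against 736 that chance gives, and DESeq2 called 31. EdgeR called 1 gene without Printex90 control 1, control 2 or control 3, and 0 without overload 2 or overload 3, which leaves the shallow library and 1 other in the group. Without overload 2 or 3, Cyp1b1 had an adjusted p = 0.0706 and 0.0857 in edgeR. The call of Ftl1 ended without any single library of the 6 (edgeR adjusted p = 0.0706 to 0.152), and that of Pld4 without any but the shallow library.

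**Figure D2:**
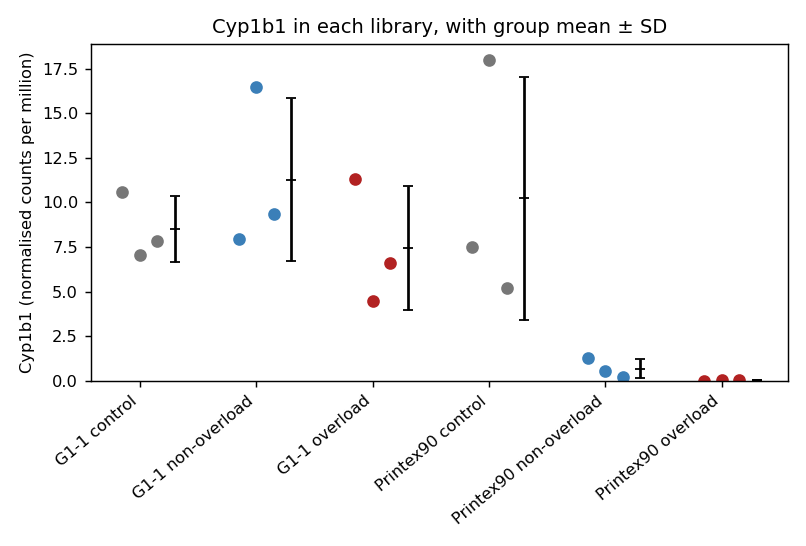
Cyp1b1 in normalised CPM (vertical axis) in each of the 18 libraries, with the mean and SD of the 3 libraries of each group beside the points. The Printex90 non-overload libraries lie between 0.226 and 1.26 and Printex90 overload 2 and 3 at 0.0200 or below, under all 12 libraries of the G1-1 groups and the Printex90 controls, while the 0 of Printex90 overload 1 has a detection floor of 6.22 and cannot be ranked.

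In Printex90 overload, genes of the NRF2 antioxidant response rose as a list, with 1 of 32 members, Ftl1, called over all genes and 4 higher when adjusted over the list alone (median 0.15, camera adjusted p = 1.72e-08, adjusted p = 0.312 with an estimated correlation). The median was 0.08 without control 2 or 3, 0.07 without overload 1 and 0.23 without control 1. Catalase (Cat, 0.36, SE 0.0846) and the autophagy receptor Sqstm1 (0.26, SE 0.0704) did not pass over all genes. NF-kB feedback and target genes fell with 21 of 27 members below their controls and 0 called over all genes or over the list alone (median -0.19, camera adjusted p = 4.43e-06, adjusted p = 0.173 with an estimated correlation). Glycolysis and hypoxia genes rose with 7 of 27 higher over the list alone and 0 over all genes (median 0.22, camera adjusted p = 1e-10, adjusted p = 0.309 with an estimated correlation). The cholesterol list fell with 0 of 24 called over all genes and 1 lower over the list alone (median -0.18, camera adjusted p = 9.89e-07, adjusted p = 0.248 with an estimated correlation). The 1 was 0 without any single control, 2 without overload 1 and 7 without overload 2. Lysosome genes (median 0.03), autophagy genes (0.05), integrated stress response genes (0.05), oxidative phosphorylation genes (0.04), metal and iron handling genes (0.10) and histones (0.17) rose and mitochondrially encoded transcripts (-0.16) fell by the preset test alone, with adjusted p = 0.173 to 0.77 in camera with an estimated correlation. Of these, Ftl1 in the metal and iron list was called over all genes, and 1 lysosome, 2 autophagy and 2 metal and iron genes were higher over the list alone. All but metal and iron lost the call without single libraries: lysosome and autophagy genes without control 2, overload 2 or overload 3 (camera adjusted p = 0.0654 to 0.354), stress response genes without control 1, overload 2 or overload 3 (0.0525 to 0.213), oxidative phosphorylation without control 1 or 2 or overload 2 or 3 (0.0674 to 0.663), histones without control 1, control 3 or overload 2 (0.213 to 0.346) and mitochondrial transcripts without control 3 or overload 1 (0.0978 and 0.261). Fibroblast and smooth muscle markers were higher (median 0.77, 0 of 13 called, camera adjusted p = 0.0422, adjusted p = 0.765 with an estimated correlation), a call lost without control 1, control 3 or overload 2 (camera adjusted p = 0.328, 0.28 and 0.299), and their score was 2.35 and 1.96 in the deep overload libraries. Of 36 lists 12 passed, 9 up and 3 down, 6 passed without overload 2, and 0 with an estimated correlation (lowest adjusted p = 0.173).

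Cyp1b1 also fell at the non-overload condition of Printex90, to 1.26, 0.539 and 0.226 CPM. Pooled, this was 7.32% of the control level (104 against 1613 counts, 95% exact interval 5.94% to 8.93%). The interval covers counting error only, not the spread between libraries, and control 2 alone held 951 of the 1613 counts. The log2 change was -3.86 (SE 0.533, edgeR adjusted p = 0.0151). The aryl hydrocarbon receptor targets, the list that holds Cyp1b1, fell with 1 of 10 called (median -0.08, camera adjusted p = 0.023, adjusted p = 0.463 with an estimated correlation). This call was lost without control 2 (median -0.04, camera adjusted p = 0.128), without non-overload 2 (-0.04, 0.115) and in the covariate fit (-0.04, 0.09), and the median was -0.19 without non-overload 3. The integrated stress response list rose with 0 of 34 called (median 0.07, 0.04 without control 1, camera adjusted p = 0.000515, adjusted p = 0.463 with an estimated correlation), while the cholesterol list had a median of 0.01 and did not pass (camera adjusted p = 0.67). Fibroblast and smooth muscle markers had a median of -1.41 (0 of 13 called, camera adjusted p = 0.0055, adjusted p = 0.802 with an estimated correlation), which rested on Printex90 control 2: without it the median was 0.09 (camera adjusted p = 0.846), and without non-overload 1 it was -1.08 (0.0527). Neutrophil markers (median -0.38, 0 of 6 called, camera adjusted p = 0.00912, adjusted p = 0.227 with an estimated correlation) and mitochondrially encoded transcripts (-0.18, 0 of 13 called, camera adjusted p = 0.0207, adjusted p = 0.802 with an estimated correlation) were lower too. The neutrophil call was lost without non-overload 3 (camera adjusted p = 0.124) and the mitochondrial one without control 3 (-0.10, 0.115) or non-overload 2 (-0.00488, 0.931). The neutrophil median was -0.58 without non-overload 2, and the mitochondrial median was -0.28 without non-overload 1. Cyp1b1 was the 1 gene called, of 502 with an unadjusted p under 0.05, and DESeq2 called 9. EdgeR called 0 genes without Printex90 control 2, non-overload 2 or non-overload 3, where Cyp1b1 had an adjusted p = 0.0533, 0.31 and 0.149. Of the lists 8 passed the preset test, 5 without non-overload 1, and 0 with an estimated correlation.

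Between the exposure conditions of Printex90 no gene passed. Cyp1b1 stood at 2.62% of its non-overload level in overload (2 against 104 counts, 95% exact interval 0.313% to 9.69%, counting error only). EdgeR did not call this fall (log2 change -5.01, SE 1.15, adjusted p = 0.422) and DESeq2 did (adjusted p = 0.00211). Plau, the urokinase gene, stood at 81.38 ± 10.4 against 130.9 ± 5.3 CPM (SD, n = 3 each; -0.63, SE 0.114, edgeR adjusted p = 0.196). The cholesterol list was lower in overload with 4 of 24 lower over the list alone (0 without non-overload 3, 1 without non-overload 1 or overload 3, 7 without overload 1) and 0 over all genes (median -0.18, camera adjusted p = 1.7e-06, adjusted p = 0.338 with an estimated correlation), and NF-kB feedback and target genes with 1 of 27 and 0 (median -0.17, camera adjusted p = 4.36e-05, adjusted p = 0.319 with an estimated correlation). NRF2 genes were higher with 3 of 32 over the list alone and 0 over all genes (camera adjusted p = 0.000171, adjusted p = 0.994 with an estimated correlation), a call lost without Printex90 overload 1 (camera adjusted p = 0.176), and fibroblast and smooth muscle markers were higher with 0 of 13 called (median 2.02, camera adjusted p = 4.36e-05, adjusted p = 0.932 with an estimated correlation). EdgeR called 0 genes, with 1038 at an unadjusted p under 0.05, DESeq2 called 25, and edgeR 1 without Printex90 overload replicate 1. Of the lists 5 passed, 3 up and 2 down.

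The overload effects of the particles were then compared with each other, as the Printex90 effect minus the G1-1 effect. Cyp1b1 was the 1 gene whose response differed (log2 difference -8.69, SE 1.11, edgeR adjusted p = 0.00547). With G1-1 overload it stood at 84.1% of its control level by pooled counts (95% exact interval 77.6% to 91.1%, counting error only). EdgeR did not call this change (adjusted p = 0.994). The difference was lost without Printex90 overload 2 or overload 3 (edgeR adjusted p = 0.215 and 0.194). NF-kB feedback and target genes moved apart, with 1 of 27 lower when adjusted over the list alone and 0 over all genes (median difference -0.23, camera adjusted p = 6.58e-07, adjusted p = 0.106 with an estimated correlation). The cholesterol list was higher in the difference, with 3 of 24 members higher in the difference over the list alone and 0 over all genes (median difference 0.16, camera adjusted p = 1.98e-06, adjusted p = 0.221 with an estimated correlation). The differences of Cyp51 (0.32), Insig1 (0.25) and Msr1 (-0.65) did not pass (edgeR adjusted p = 0.831, 0.845 and 0.829). In the difference 755 genes had an unadjusted p under 0.05 and DESeq2 called 10. Of the lists 8 passed, 5 without G1-1 overload 1 or without Printex90 control 1, and 0 with an estimated correlation.

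For the non-overload condition, the difference between particles reached no gene in edgeR, with 377 genes at an unadjusted p under 0.05 and 5 called by DESeq2. Cyp1b1 came closest (log2 difference -4.27, SE 0.691, edgeR adjusted p = 0.121), and it was the 1 gene called without Printex90 control 3 or without non-overload 1 (adjusted p = 0.0397 and 0.0316). The cholesterol list was higher in the difference, with 1 of 24 higher over the list alone and 0 over all genes (median 0.11, camera adjusted p = 8.93e-08, adjusted p = 0.309 with an estimated correlation). All 48 cytosolic ribosomal protein genes lay above 0 (median 0.11, 0 called, camera adjusted p = 1.53e-05, adjusted p = 0.643 with an estimated correlation), a call lost without G1-1 control 2 (median 0.03, camera adjusted p = 0.229). Of the lists 10 passed, 16 without G1-1 control 1, 6 without G1-1 control 2, and 0 with an estimated correlation.

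**Figure D3:**
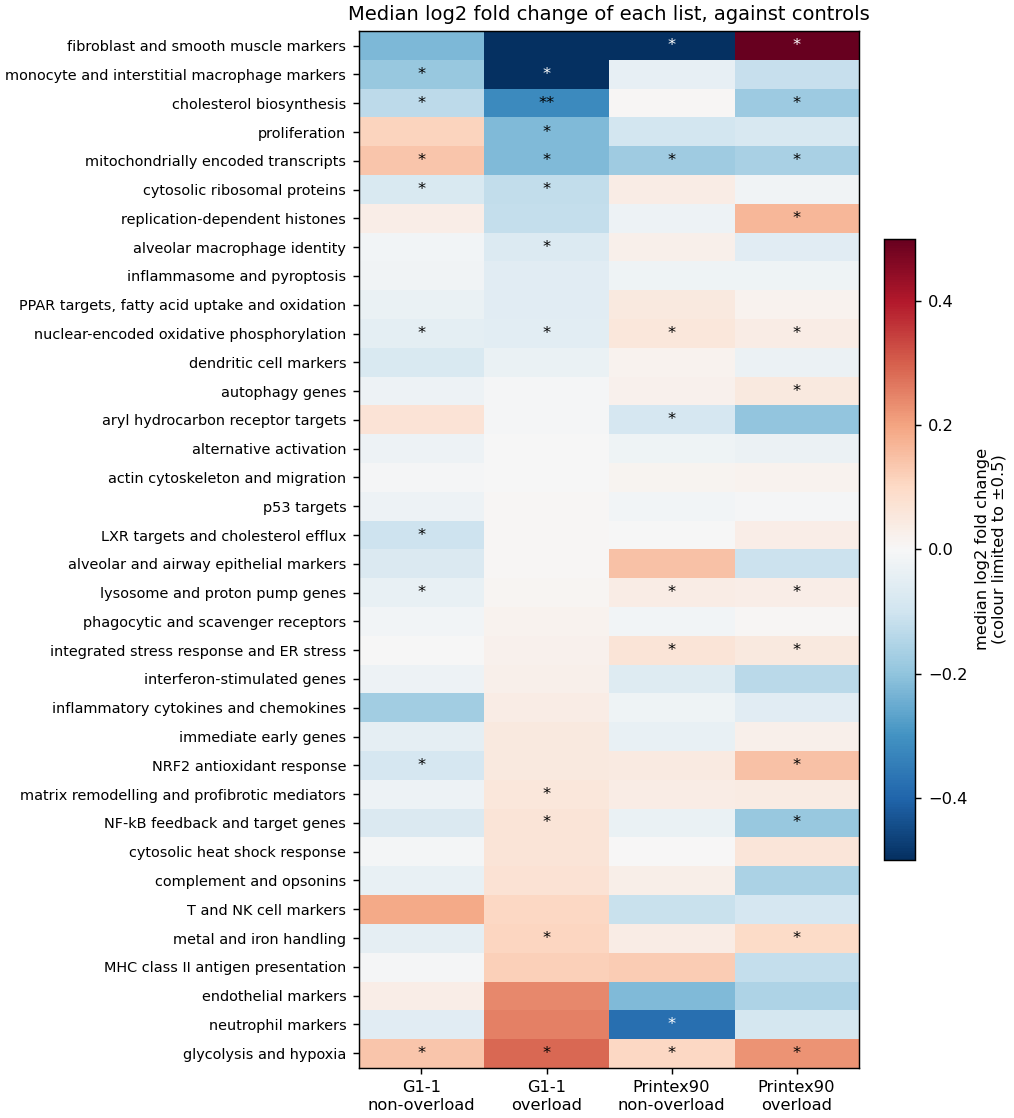
Median log2 fold change (colour, limited to 0.5 either way) of each of the 36 tested lists (vertical axis) in the 4 comparisons with controls (horizontal axis). One star marks a camera adjusted p under 0.05 with the preset correlation, and 2 stars mark one that also passes with an estimated correlation, which holds for cholesterol biosynthesis in G1-1 overload alone.

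Across the 14728 genes, the overload effects of the particles had a Pearson r of -0.0574 and a Spearman rho of -0.028, and no gene was called with both. The sign of this r depended on which library was left out. Over the 4991 genes with a mean log2 CPM of at least 5, r was 0.452 and rho 0.0878. Without Lars2, a gene picked after its values were seen that ranged from 89.8 to 8360 CPM within the G1-1 controls, r was 0.164 and rho 0.0873. Of the 22 genes called with G1-1 overload, 18 had the same sign with Printex90 overload, none of them past the threshold there. Overload and non-overload effects of a particle share control libraries. Their correlation was 0.366 with G1-1 and 0.271 with Printex90. In simulated groups with no effect it was 0.497 (SD 0.0229) and 0.429 (SD 0.022). Their covariance was 0.145 and 0.163, against 0.187 in both simulations (SD 0.0134 and 0.0132). The observed correlations lay well below those of unchanged groups, so the simulations may not describe these libraries. They cannot decide whether a relation beyond that of shared controls exists. All 22 genes called with G1-1 overload had the same sign with G1-1 non-overload, which shared controls also favour. Genes are not independent replicates, and no p is given.

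The control libraries of the particles also differed from each other. Of the genes higher in the Printex90 controls, Slc7a1, a carrier of cationic amino acids, stood at 109 ± 3.66 against 49.6 ± 4.02 CPM (SD, n = 3 each; 2.20-fold, edgeR adjusted p = 6.46e-08), and Slc7a5, Trib3 and Mthfd2 were 2.83-, 2.46- and 2.06-fold higher. The cystine carrier Slc7a11 stood at 306.8 ± 82 against 153.5 ± 11.6 CPM (edgeR adjusted p = 0.00489). The hypoxia-inducible prolyl hydroxylase Egln3 stood at 1.37 ± 1.06 against 20.3 ± 6.56 CPM (log2 difference -3.90, SE 0.498, edgeR adjusted p = 0.000179), and Gpr35, Klhl3, Ak4 and Ndrg1 were lower by -2.90, -1.95, -1.88 and -1.54 on the log2 scale. The integrated stress response list had 12 members higher and 6 lower of 34 over all genes, and 14 and 10 when adjusted over the list alone (camera adjusted p = 1.98e-08, adjusted p = 0.156 with an estimated correlation). Of 27 glycolysis and hypoxia genes, 12 were lower and 1 higher over all genes, and 18 and 2 over the list alone (camera adjusted p = 7.97e-16, adjusted p = 0.172 with an estimated correlation). Histones were lower with 2 of 24 over all genes and 10 over the list alone, mitochondrially encoded transcripts were higher with 4 of 13 and 9, and antigen presentation genes of MHC class II were lower with 2 of 12 and 5 (adjusted p = 0.156, 0.401 and 0.247 with an estimated correlation). The 2 histones called over all genes were 9 without Printex90 overload 1 and 4 without G1-1 control 3 or Printex90 control 2. The 10 over the list alone ran from 2 without Printex90 control 3 and 3 without G1-1 control 2 to 17 without Printex90 control 2, with 6 without G1-1 control 1. The 4 mitochondrial genes were 0 without G1-1 control 1 or 2 and 1 without Printex90 control 1 or 3. The 13 glycolysis and hypoxia genes called were 7 without G1-1 control 2 or Printex90 control 3 and 8 without Printex90 control 2. The 5 MHC class II genes were 2 without G1-1 control 2 or Printex90 control 2, 3 without G1-1 control 1 or Printex90 control 3 and 8 without Printex90 control 1. With the replicate block the MHC class II list did not pass (camera adjusted p = 0.115), and 0 of its members were called over all genes. The genes called were then 0 mitochondrial, 2 of glycolysis and hypoxia, 8 of the integrated stress response and 2 histones.

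Between the 2 sets of controls 392 genes differed in edgeR, 178 higher and 214 lower. The count was 217 without G1-1 control 1, 144 without G1-1 control 2, 208, 209 and 176 without Printex90 control 1, 2 and 3, and 797 without Printex90 overload replicate 1. It was 11 against a fold of 1.5. Of the lists 8 passed, 5 without Printex90 control 1, and 0 with an estimated correlation. Each comparison of a particle with controls uses the controls of its own set.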

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

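The tests of explanations below were chosen after the results were seen. The response of Cyp1b1 to overload differed between the particles (edgeR adjusted p = 0.00547, log2 difference -8.69, with 1 count each in Printex90 overload 2 and 3). Fewer stromal cells, a possible source of Cyp1b1, do not account for its fall: Printex90 overload 2 and 3, with fibroblast scores of 2.35 and 1.96, had the highest scores of the Printex90 exposed groups, and with the score as a covariate and no shallow library the change was -9.14 (SE 0.893, edgeR adjusted p = 0.00017). The shallow library does not account for it either, since without it the edgeR adjusted p was 0.00198 (1.99e-16 in DESeq2 to 0.0857 without overload 3 over all alternatives). Lower activity of the aryl hydrocarbon receptor may be a cause. Its other 9 tested targets had a median of -0.181 (quartiles -0.272 and 0.144), 5 of them lower, with Tiparp at 0.02 (SE 0.0958). The 5 include the receptor gene Ahr itself (-0.272) and Cyp1a1 and Serpinb2, at a mean log2 CPM of -2.41 and -1.84. The median is that of Nfe2l2, which was -0.0511 without the shallow library. Nqo1 went from 0.414 to -0.094 without it. Cyp1a1, near the floor, had 63 counts in Printex90 control 2 and 0 in the other Printex90 controls and the Printex90 overload libraries. With G1-1 it had 31, 0 and 0 in controls and 0, 5 and 2 in overload. By the bound first set, these values counted against the receptor. That bound was replaced after they were seen, because targets can differ in their dependence on it. Under the new bound only a rise of the other targets, with both quartiles above 0, would count against the receptor. Unchanged targets could not, so this test cannot decide. No verdict is drawn, and an effect on Cyp1b1 alone also stays open.

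The cholesterol list passed in the difference between overload effects (camera adjusted p = 1.98e-06, adjusted p = 0.221 with an estimated correlation). Of 40 splits, 2, the real one included, gave as low a value (4.27e-31 in the other). A split can keep the fall with G1-1 overload while it mixes the Printex90 libraries. The splits therefore cannot test the difference between particles, and chance is not excluded for it. The values give no sign that fibroblast or muscle cell content accounts for the fall with G1-1 overload. With the score as a covariate and no shallow library all 9 called members were still lower when adjusted over the list alone, with a list median of -0.32. The scores overlapped between the groups (2.438, 1.065 and 0.745 in controls, 1.138, 1.324 and 1.305 in overload), so the covariate had little difference to remove. The shallow library does not account for the fall, since 12 members fell over all genes without it. An excess of sterol in the cells could lower these genes and would raise the liver X receptor targets, whose median was 0.00547 (quartiles -0.0765 and 0.0551), 9 of 17 higher. A median near 0 over genes that go both ways leaves this explanation open.

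The following values are given without an explanation. In the difference between overload effects, camera also passed NF-kB feedback and target genes (adjusted p = 6.58e-07), NRF2 antioxidant response (0.000677), aryl hydrocarbon receptor targets (0.0241), nuclear-encoded oxidative phosphorylation (0.000242), cytosolic ribosomal proteins (0.00197), replication-dependent histones (0.0124) and fibroblast and smooth muscle markers (0.0298). In the difference between non-overload effects it passed NRF2 antioxidant response (adjusted p = 0.00114), lysosome and proton pump genes (0.000205), cholesterol biosynthesis (8.93e-08), liver X receptor targets (0.0385), PPAR targets (0.0151), integrated stress response (0.00382), aryl hydrocarbon receptor targets (0.00897), nuclear-encoded oxidative phosphorylation (1.02e-06), cytosolic ribosomal proteins (1.53e-05) and mitochondrially encoded transcripts (0.000427). None of these lists passed camera with an estimated correlation (adjusted p = 0.106 to 0.841). In the preset test, NF-kB genes and oxidative phosphorylation for overload, and cholesterol biosynthesis, integrated stress response and oxidative phosphorylation for non-overload, passed in all alternatives with that test, and each of the others was lost in at least 1. Entries with no gene name took 0.0709% of the counts of Printex90 overload replicate 1, above the highest control share of 0.0197%, and 0.015% to 0.0223% in the other libraries.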

How the results depend on the processing

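The fit with the fibroblast score as a covariate, and the omission of Printex90 overload 1 where it is not compared, were chosen after the data were seen. Counts of genes depended on the tool and on single libraries, and those of lists on the correlation assumed. For G1-1 overload against control (22 in edgeR) DESeq2 called 111, the 9 libraries of the particle alone 4, the replicate block 4, the test against a fold of 1.5 0, the covariate fit 107, RLE 28 (13 up, 15 down), and omissions 2 (without overload 3) to 81 (without Printex90 overload 1). For G1-1 non-overload (0 in edgeR, 481 at an unadjusted p under 0.05) these were DESeq2 12, no filter 4, omissions 0 to 1. Between G1-1 conditions (2) they were DESeq2 38, no filter 8, stricter filter 1, block 0, fold test 0, covariate 15, omissions 0 to 19. For Printex90 overload (3) they were RLE 5, DESeq2 31, fold test 1, omissions 0 to 3, and for Printex90 non-overload (1) DESeq2 9, omissions 0 to 1. Between Printex90 conditions (0 in edgeR, 1038 at an unadjusted p under 0.05) they were DESeq2 25, no filter 8, 9 libraries 1, covariate 2, omissions 0 to 1. The overload difference (1) gave DESeq2 10, omissions 0 to 1, the non-overload difference (0 in edgeR, 377 at an unadjusted p under 0.05) DESeq2 5, no filter 1, omissions 0 to 1, and the controls (392) block 78, fold test 11, covariate 850, omissions 144 (without G1-1 control 2) to 797 (without Printex90 overload 1). In the same order of comparisons, lists past the threshold were 11, 9, 10, 12, 8, 5, 8, 10 and 8, with an estimated correlation 1, 0, 1, 0, 0, 0, 0, 0 and 0, and over omissions 6 to 11, 3 to 10, 9 to 13, 6 to 14, 5 to 10, 5 to 7, 5 to 11, 6 to 16 and 5 to 9. Over omissions the correlation of overload effects between particles was -0.234 to 0.0655, and that of overload with non-overload 0.269 to 0.526 for G1-1 and 0.184 to 0.477 for Printex90. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.275 to 0.231.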

Other observations

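The comparison of the control difference with the exposed groups was set before its values were seen, and the splits and the covariate fit were chosen after the data were seen. In culture without particles, in the G1-1 controls, the alveolar macrophage genes Siglecf, Itgax and Pparg stood at 582.6 ± 23.4, 2968 ± 134 and 111.4 ± 1.64 CPM (SD, n = 3), whereas the scavenger receptor Marco stood at 2.56 ± 0.722 CPM. The lysosomal protease Ctsd stood at 28300 ± 1590, the membrane glycoprotein Gpnmb at 18750 ± 1210, the elastase Mmp12 at 4096 ± 167 and the secreted protein Spp1 at 800.7 ± 81 CPM.

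Inflammatory cytokines were not moved past the threshold by overload with either particle, apart from the fall of Il18 with G1-1. With G1-1, Tnf (0.14, SE 0.174), Il1a (-0.01, SE 0.0881), Il1b (-0.30, SE 0.73) and the chemokine Cxcl2 (1.01, SE 0.44) had an edgeR adjusted p = 0.608 to 1. With Printex90 the same genes stood at -0.06, -0.01, -0.49 and -0.65 (edgeR adjusted p = 1 each). Il1b was under 1 CPM in the controls, and Il6 was listed at 0 in them and was not tested. The list of 21 tested cytokines and chemokines did not pass in either overload comparison (camera adjusted p = 0.632 and 0.505).

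The difference between the control sets holds for the exposed cells. Of the 392 genes called between controls, 390 (99.5%) differed the same way between the non-overload groups and 386 (98.5%) between the overload groups, against 64.1% and 65.3% of all tested genes, with no library in common. The fibroblast scores of the control sets were alike (2.438, 1.065 and 0.745 with G1-1, 1.031, 2.405 and 0.9557 with Printex90). They give no sign that fibroblast content accounts for the difference. The fit with the score as a covariate and no shallow library called 850 genes, against 797 without the shallow library and no covariate. A score balanced between the sets cannot remove a difference between them, so that fit is no test of this. The set is confounded with the particle, and the labels do not say what else differed between the sets, such as the day or the animals. Differences between particles were for this reason tested on the effects against each set's own controls.

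Exchanging libraries between groups gives 10 splits of 6 libraries, too few for a share under 0.05. The real and the highest other gene counts were 22 and 0 for G1-1 overload against control, 2 and 0 between G1-1 conditions, 3 and 0 for Printex90 overload, 1 and 0 for Printex90 non-overload and 392 and 0 for the controls, each with 1 split of 10 as high, and 0 and 0 for G1-1 non-overload and 0 and 1 between Printex90 conditions, each with 10 of 10. For lists, in the same order, they were 11 and 17 (3 splits as high), 10 and 12 (2), 12 and 6 (1), 8 and 9 (3), 8 and 9 (6), 9 and 10 (4) and 5 and 4 (1). For the overload difference 4 of 40 splits gave as many genes (1 and 1) and 8 of 40 as many lists (8 and 11), and for the non-overload difference 40 of 40 (0 and 43) and 7 of 40 (10 and 15). Where the real gene count is 0, every split is as high by construction, so its share tests nothing. Exchange within a particle can also keep a real effect of 1 particle, so these splits cannot test the difference between effects. Chance is not excluded for the other counts. A split with 43 genes where the real one has 0, and another with 22, point to a structure of the samples, whose nature was not tested. The cholesterol list passed camera's preset test in the 9 other splits of G1-1 overload and control too, with the lowest adjusted p = 0.000104 against 2.57e-42. Each of these splits still separates the groups in part, so a real effect could also make the list pass there. Between Printex90 conditions another split gave a lower camera adjusted p than the real one, 4.64e-09 against 1.7e-06. The preset p values of lists are for this reason not to be read at face value.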
